A study of Mus musculus with 9 samples.

How the data were processed

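Total RNA of the hMLKL1-181-2Fv-NIH3T3 mouse cell line was measured on 9 one-colour Affymetrix arrays, 3 for each of 3 groups taken from the treatment labels: control, B/B for 1 h with annexin V-positive cells sorted, and the same followed by 6 h of washout. Doses of 50 nM for B/B and 3000 nM for the washout, whose compound is not named, came from the series design. RNA was extracted with Trizol and biotin-labelled cRNA was prepared, per the labels' protocols. Partek 6.6 was used, per the submitters' processing notes, and the method of summary and normalization was not given in the sources used here. The deposited values were log2 probe set summaries already normalized between arrays, as read from the values themselves, which had near-equal quantiles on the 9 arrays. Base 2 was inferred from a maximum near that of scanner intensities, which is a limit of every fold given. No detection calls were used here.

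Of 41345 probe sets, 23521 carried 1 gene symbol, 1814 several and 16010 none. A gene table of mouse assembly GRCm38.p6 was used only for names, biotypes and which genes span which, and it held the gene IDs of 23328 of the 1-symbol probe sets and not of the other 193. It changed 0 symbols. Probe sets with 1 symbol gave 22180 genes, of which 1082 had over 1 probe set, and the probe set with the highest mean over all arrays stood for its gene. Probe sets of 1 gene were called in opposite directions in 4, 9 and 12 of these genes for B/B 1 h against control, washout against control and washout against B/B 1 h. Probe sets with several symbols or none were fitted apart, each kind with its own Benjamini-Hochberg adjustment.

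Groups were compared in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, in 1 linear model of 3 group means over all 9 arrays with moderated t-tests and an F-test. Adjusted p under 0.05 after Benjamini-Hochberg adjustment within each comparison was the threshold. The fit had 6 residual degrees of freedom and a prior of 3.38, and the median standard error of a log2 difference was 0.0636. The number of arrays, 3 per group, limits the precision. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over 63 tests of 21 lists in 3 comparisons. These covered chemokines and cytokines, NF-kB, immediate-early, type I interferon, unfolded protein and integrated stress, heat shock, ESCRT, necroptosis, p53, cell cycle, cholesterol, NRF2, hypoxia and glycolysis, extracellular matrix, membrane repair, nuclear-retained long noncoding RNA, ribosomal protein and oxidative phosphorylation genes, with markers of leukocytes, epithelium and endothelium. The list named nuclear-retained long noncoding RNA also holds snoRNA host RNA such as Snhg1 and Snhg12. Where its members lie in the cell was not measured. Some list members have no 1-symbol probe set among the probe sets used and were not analysed here, so that each list is given by its measured members.

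Genes named were, for each comparison, the 8 highest and 8 lowest by log2 difference among those past the threshold whose groups did not overlap, leaving out predicted-gene names, up to 3 members of each list in each comparison with control, and Mlkl and Ripk3. A gene among the 8 highest between washout and B/B 1 h is not reported here. Whether the probe set of mouse Mlkl also measures the human fusion transcript was not examined. Genes that moved back were those called in 1 direction at 1 h and in the other between 1 h and washout. Baselines for overlaps were the product of the list sizes and 100 simulations of unchanged groups that shared arrays as the real comparisons did. Other regroupings of the arrays numbered 10 for each pair of groups and 100, drawn with a fixed seed, for all 3. Gene sets chosen after the data were seen were also tested without the genes the naming rule picks. Bootstrap intervals used 2000 draws at the 95% level.

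Alternatives were quantile normalization, array medians centred, the lowest 30% of genes by mean left out, probe sets averaged, a mean-variance trend, a robust variance prior, no moderation, array weights, only the 2 groups compared, every probe set tested on its own, adjusted p under 0.01, and each array left out in turn. List tests were also run with an estimated correlation and with fry. Camera tests a list against the other genes and fry tests it against no change, which is another hypothesis, so ranges over the alternatives of a list are those of camera. A quality reading from control probe sets was not made, since the tables used here do not name them, and an alternative for linear values did not apply. Without moderation there is no list test, a variance trend and a robust prior leave camera as it is, and only 2 groups give no F-test.

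The code was tested on simulated data with 200 of 22180 genes changed, 50 at each of 4 folds. Of genes changed 1.25-fold, 68%, 60% and 70% were recovered in the 3 comparisons, and of those changed 1.5-fold 100%, 94% and 96%. All of those changed 2-fold and 4-fold were recovered. False calls were 10 of 194, 9 of 186 and 6 of 189, and 0 of 60 camera tests of 20 unchanged lists were called. Genes were simulated independently of each other, so this gives no rate of false list calls for correlated genes. In the real lists the estimated inter-gene correlation reached 0.222, for oxidative phosphorylation.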

Results

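Gene expression was measured on 9 one-colour Affymetrix arrays, 3 per group, in an NIH3T3 mouse fibroblast line that carried part of human MLKL fused to Fv domains. MLKL is the pseudokinase that permeabilizes the plasma membrane in necroptosis, and B/B is a compound that brings Fv domains together and so dimerizes the fusion protein. Control cells were compared with cells given 50 nM B/B for 1 h and sorted for annexin V, a protein that binds phosphatidylserine exposed on the cell surface. The third group was treated and sorted in the same way and then kept for 6 h of washout, which the series design gives as 3000 nM without naming the compound. The labels do not say whether control cells were sorted, or when they were harvested. Effects of B/B, sorting and harvest time therefore cannot be told apart in comparisons with control. Array medians lay between 4.60 and 4.68 on the log2 scale, where base 2 was inferred from the values. Across genes, which are not independent replicates, arrays of a group correlated at 0.998 to 0.999 and arrays of different groups at 0.990 to 0.998. The number of arrays limits the precision of every value given here.

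Among 22180 genes tested, 6542 differed among the 3 groups (limma moderated F-test, Benjamini-Hochberg adjusted p under 0.05). The first principal component held 62.1% of the variance and parted the washout arrays, at 26.3 to 28.0, from the other 6, at -17.9 to -10.8. PC2 held 14.0% and parted control arrays, at 9.48 to 13.2, from B/B 1 h arrays, at -16.2 to -5.04. B/B 1 h replicate 1 lay farthest out on PC2 and had the lowest array weight, 0.563.

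**Figure D1:**
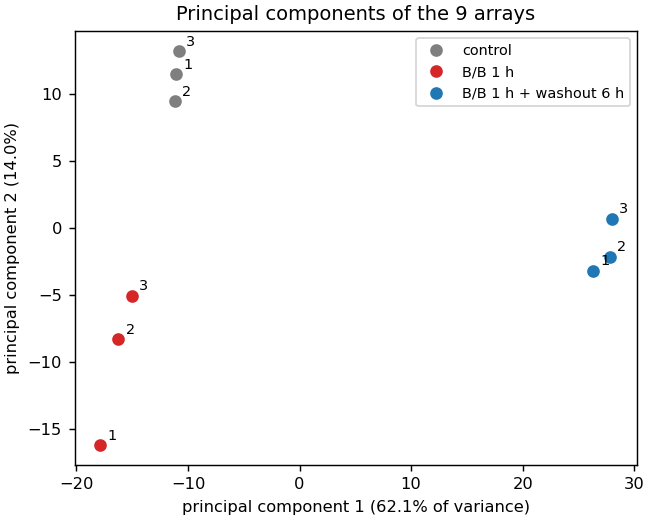
Principal components of the 9 arrays over 22180 genes, with PC1 (62.1% of variance) on the x axis, PC2 (14.0%) on the y axis and 1 point per array coloured by group. The 3 washout arrays sit at PC1 of 26.3 to 28.0, and the control and B/B 1 h arrays part along PC2.

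The comparison of B/B 1 h with control asked which transcripts differed in cells that exposed phosphatidylserine 1 h after MLKL dimerization began. Cxcl10 and Cxcl1, chemokines that draw T cells and neutrophils, rose 8.40-fold and 7.75-fold. The log2 level of Cxcl10 went from 5.09 ± 0.047 to 8.16 ± 0.046 (SD, n = 3 per group) and that of Cxcl1 from 6.39 ± 0.22 to 9.34 ± 0.049 (SD, n = 3 per group). Tnfaip3, which encodes a deubiquitinase that shuts off NF-kB signalling, rose 4.28-fold, and Fos, an AP-1 transcription factor subunit, rose 3.86-fold. Hspa1b, an inducible chaperone gene, and Rcan1, a calcineurin inhibitor gene that calcium signalling induces, rose 2.95-fold and 3.08-fold. The highest Benjamini-Hochberg adjusted p of these 6 genes in limma was 2.7e-06, for Fos, and each was higher in all 3 B/B 1 h arrays than in any control array. The labels do not say whether the samples of a group were separate cultures, so the p-values measure spread between these samples, which can be technical.

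At 1 h, 642 genes passed the threshold, 224 higher and 418 lower, and 39 of them changed at least 2-fold, 24 up and 15 down. The share that was higher, 34.9%, was 48.0% with quantile normalization and 46.1% without control replicate 3. The count of 642 was 359 with only the 2 groups in the limma fit and 1228 with a variance trend. It was 376, 372 and 323 without control replicates 1, 2 and 3, and 369 and 422 without B/B 1 h replicates 1 and 2. In 4723 genes (21.3%) the 3 arrays of each group did not overlap, where chance gives 10%.

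Of the chemokine and cytokine list, 5 higher and 0 lower of 25 measured members passed the threshold (6 and 0 adjusted over the list alone, 7 and 0 by limma at unadjusted p under 0.05), and Lif, an IL-6 family cytokine, rose by 0.77 ± 0.086 (log2, SE). Cxcl2 at 0.68 and Ccl7 at 0.22 made up the 5 and were chosen after their values were seen. The camera test called the list up at an adjusted p of 6.5e-05, with adjusted p = 0.0918 with an estimated correlation, the highest of its camera alternatives, which began at 7.8e-06. Among NF-kB feedback and target genes, 6 higher and 2 lower of 25 passed (11 and 3 adjusted over the list alone). Nfkbiz, a nuclear IkB-like co-regulator, rose by 1.31 ± 0.061 and Nfkbia, the inhibitor that holds NF-kB in the cytosol, by 1.03 ± 0.041 (log2, SE). Gadd45b, a stress sensor that NF-kB induces, fell by 0.66 ± 0.063 (log2, SE) against the list, as did Tnfaip2, chosen after its value was seen, by 0.27. The list was called up at a camera adjusted p of 1.7e-04, with adjusted p = 0.172 with an estimated correlation, the highest of camera alternatives from 3.3e-05. The type I interferon list had 1 higher and 0 lower of 24 (1 and 0 adjusted over the list alone, 4 and 0 by limma at unadjusted p under 0.05) and a camera adjusted p of 0.0976. Its 1 higher gene was Stat2, a transcription factor of interferon signalling, at 0.35 (log2).

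Immediate-early genes, transcribed within minutes of a stimulus without new protein, had the largest share of moved members among the 21 lists at 1 h, with 26 higher and 1 lower of 38 past the threshold (29 and 2 adjusted over the list alone). Btg2, an antiproliferative co-regulator, rose by 1.46 ± 0.060, Jund, an AP-1 subunit, by 1.18 ± 0.068 and Egr1, a zinc finger transcription factor, by 0.95 ± 0.050 (log2, SE). Klf10, a TGF-beta-inducible repressor, was the member that fell, by 0.36 ± 0.050 (log2, SE). The list's camera adjusted p was 3.2e-31 and stayed under the threshold, at 0.0286, with an estimated correlation. Of heat shock genes, 3 higher and 0 lower of 17 passed (4 and 0 adjusted over the list alone, 5 and 0 by limma at unadjusted p under 0.05), namely Hspa1b, Dnajb1, its co-chaperone, at 1.12 and Bag3, a nucleotide exchange factor, at 0.24 (log2). Camera called the list up at an adjusted p of 1.4e-04, and of 0.0286 with an estimated correlation. In the unfolded protein and integrated stress response list, 5 higher and 2 lower of 26 passed (5 and 6 adjusted over the list alone) and no camera call was made (adjusted p 0.577). Ppp1r15a, a phosphatase subunit that restarts translation, Chac1, a glutathione-degrading enzyme, and Ddit3, a stress transcription factor, rose by 1.04, 0.75 and 0.59 (log2), with the reticulum chaperone genes Dnajb9 at 0.43 and Hspa5 at 0.28 chosen after their values were seen. The list's median, -0.05, and its tested direction, down, differed in sign from its mean, 0.04. Ddit4, an mTORC1 inhibitor, and Slc7a11, the cystine importer, fell by 0.21 and 0.35 (log2), and the Slc7a11 value was -0.13 with its probe sets averaged (adjusted p 0.287; 5.0e-04 to 0.287 over its alternatives).

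Cholesterol genes were called up at 1 h, with 2 higher and 0 lower of 19 past the threshold (3 and 0 adjusted over the list alone, 8 and 0 by limma at unadjusted p under 0.05) and a camera adjusted p of 8.5e-06, with adjusted p = 0.0918 with an estimated correlation, the highest of camera alternatives from 3.7e-07. Hmgcs1, an early enzyme of the pathway, and Insig1, which retains its transcription factor in the endoplasmic reticulum, rose by 0.40 and 0.34 (log2). The p53 target list was called down, at a camera adjusted p of 0.00384, with adjusted p = 0.0918 with an estimated correlation, the highest of camera alternatives from 5.6e-04. Its moved members were Phlda3, an AKT inhibitor that fell by 0.48, and Plk2, a kinase that rose by 0.39 (log2), or 1 higher and 1 lower of 18 (1 and 4 adjusted over the list alone).

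The series title concerns the ESCRT machinery, which buds and severs membranes. Of its measured genes, 0 higher and 1 lower of 29 passed at 1 h (0 and 1 adjusted over the list alone, 0 and 5 by limma at unadjusted p under 0.05; camera adjusted p 0.336). That gene was Vps37b, an ESCRT-I subunit, at -0.42 ± 0.064 (log2, SE). In the necroptosis and death receptor list, 1 higher and 0 lower of 19 passed (1 and 0 adjusted over the list alone, 1 and 2 by limma at unadjusted p under 0.05; camera adjusted p 0.608), the ubiquitin ligase gene Birc3 at 0.24 (log2). The probe set of mouse Mlkl read 9.61 ± 0.083 in control and 9.49 ± 0.037 at 1 h (log2, SD, n = 3 per group; limma adjusted p 0.247). Ripk3, the kinase that phosphorylates MLKL, read 4.48 ± 0.21 and 4.41 ± 0.15 (log2, SD, n = 3 per group; limma adjusted p 0.817), and its log2 difference ran from -0.17 to 0.05 over the alternatives. Membrane repair and calcium-binding genes had 0 higher and 1 lower of 25 (0 and 1 adjusted over the list alone, 0 and 3 by limma at unadjusted p under 0.05; camera adjusted p 0.674), the caveola coat gene Cavin1 at -0.27 (log2).

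Camera did not call the cell cycle, matrix, ribosomal protein, oxidative phosphorylation, nuclear-retained RNA, NRF2 or hypoxia lists at 1 h. Some members of each passed the threshold. Cell cycle genes had 0 higher and 1 lower of 30 (0 and 1 adjusted over the list alone, 1 and 4 by limma at unadjusted p under 0.05; camera adjusted p 0.161), the replication licensing factor Cdt1 at -0.22. Extracellular matrix genes had 0 higher and 1 lower of 29 (3 and 2 adjusted over the list alone, 6 and 5 by limma at unadjusted p under 0.05; camera adjusted p 0.922), the protease inhibitor Timp1 at -0.25, with a median above 0, a mean of -0.01 and a tested direction of down. Ribosomal protein genes had 0 higher and 1 lower of 36 (0 and 2 adjusted over the list alone, 1 and 4 by limma at unadjusted p under 0.05; camera adjusted p 0.161), Rpl37 at -0.55, which was lost with only the 2 groups compared (adjusted p 0.0558; 0.00318 to 0.0598 over its alternatives). Oxidative phosphorylation genes had 0 higher and 2 lower of 33 (0 and 4 adjusted over the list alone, 2 and 6 by limma at unadjusted p under 0.05; camera adjusted p 0.0707), Uqcrfs1 of complex III at -0.36 and Ndufs3 of complex I at -0.27. Nuclear-retained long noncoding RNA had 1 higher and 1 lower of 11 (1 and 1 adjusted over the list alone; camera adjusted p 0.674), Snhg1 at 0.26 and Dleu2 at -0.94 (-0.60 with its probe sets averaged), with a median of 0.08 and a mean of -0.04. Antioxidant NRF2 targets had 2 higher and 2 lower of 16 (3 and 4 adjusted over the list alone; camera adjusted p 0.258), with the heme-degrading enzyme gene Hmox1 at 0.50 and the autophagy receptor gene Sqstm1 at 0.31, and its lower members were Slc7a11 and, chosen after its value was seen, the pentose phosphate gene Pgd at -0.20. Hypoxia and glycolysis genes had 1 higher and 1 lower of 23 (1 and 4 adjusted over the list alone; camera adjusted p 0.381), the stress-responsive gene Ndrg1 at 0.20 and the angiogenic factor Vegfa at -0.32, with a median of 0.01, a mean of -0.04 and a tested direction of down.

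Markers of other cell types were measured beside these groups. Of leukocyte markers, 3 higher and 0 lower of 13 passed (4 and 1 adjusted over the list alone, 4 and 1 by limma at unadjusted p under 0.05) at a camera adjusted p of 0.0263, with adjusted p = 0.147 with an estimated correlation. Cd14, the lipopolysaccharide co-receptor, rose by 0.61 ± 0.060, Cd68, a lysosomal glycoprotein, by 0.51 ± 0.071 and Adgre1, a macrophage surface receptor, by 0.30 ± 0.064 (log2, SE), while the pan-leukocyte gene Ptprc stood at -0.05 and the lysozyme gene Lyz2 at -0.26. The list's call ended with quantile normalization (adjusted p 0.0717) and without control replicate 2 (0.0507), B/B 1 h replicate 1 (0.0667) or B/B 1 h replicate 3 (0.0525), within 0.00367 to 0.147 over its camera alternatives. Adgre1, Lyz2 and Ptprc were in the lowest 30% of genes by mean, where signal was not told apart from background. Epithelial markers had 0 higher and 0 lower of 12 (0 and 0 adjusted over the list alone, 1 and 1 by limma at unadjusted p under 0.05; camera adjusted p 0.587), with the tight junction gene Cldn4 at 0.22 (0.07 to 0.36 over the alternatives). Endothelial markers had 0 higher and 0 lower of 11 (0 and 1 adjusted over the list alone, 3 and 1 by limma at unadjusted p under 0.05; camera adjusted p 0.0951), with the cadherin gene Cdh5 at -0.25.

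The lowest values at 1 h belonged to small noncoding RNA genes. Mir199b, Mir677 and Mir19a, which encode microRNA, fell by 2.11 ± 0.22, 1.81 ± 0.11 and 1.44 ± 0.13 (log2, SE). Snora34, Snord110 and Snora44, which guide RNA modification, fell by 1.97, 1.43 and 1.30, and Rny3, a Y RNA, and Scarna6, a Cajal body RNA, by 1.19 and 1.16 (log2). Against these, Mir1938 rose 6.47-fold and Lsmem1, a membrane protein gene, 6.69-fold. The Scarna6 call was lost without moderation of the variance (adjusted p 0.0575; 0.00129 to 0.0575 over its alternatives).

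Several members named at 1 h lay close to the threshold, and their calls were lost when 1 array was left out. These arrays included washout arrays, which enter this comparison only through the estimate of spread. The calls of Birc3, Ndrg1, Snhg1 and Adgre1 were lost without any 1 of the 9 arrays, with adjusted p up to 0.114, 0.108, 0.117 and 0.130. Cdt1 was lost without any array but washout replicate 3 (up to 0.136), Timp1 without any but B/B 1 h replicate 3 (up to 0.123), and Ndufs3 without any but control replicate 1 (up to 0.0942). Cavin1 was lost without any control array, B/B 1 h replicate 1 or 3, or washout replicate 2 (up to 0.104). Uqcrfs1 was lost without any control array, B/B 1 h replicate 1 or 2, or washout replicate 1 (up to 0.162). Over all alternatives the adjusted p of these 9 genes ran from 0.00125, for Ndrg1, to 0.604, for the same gene with its probe sets averaged.

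**Figure D2:**
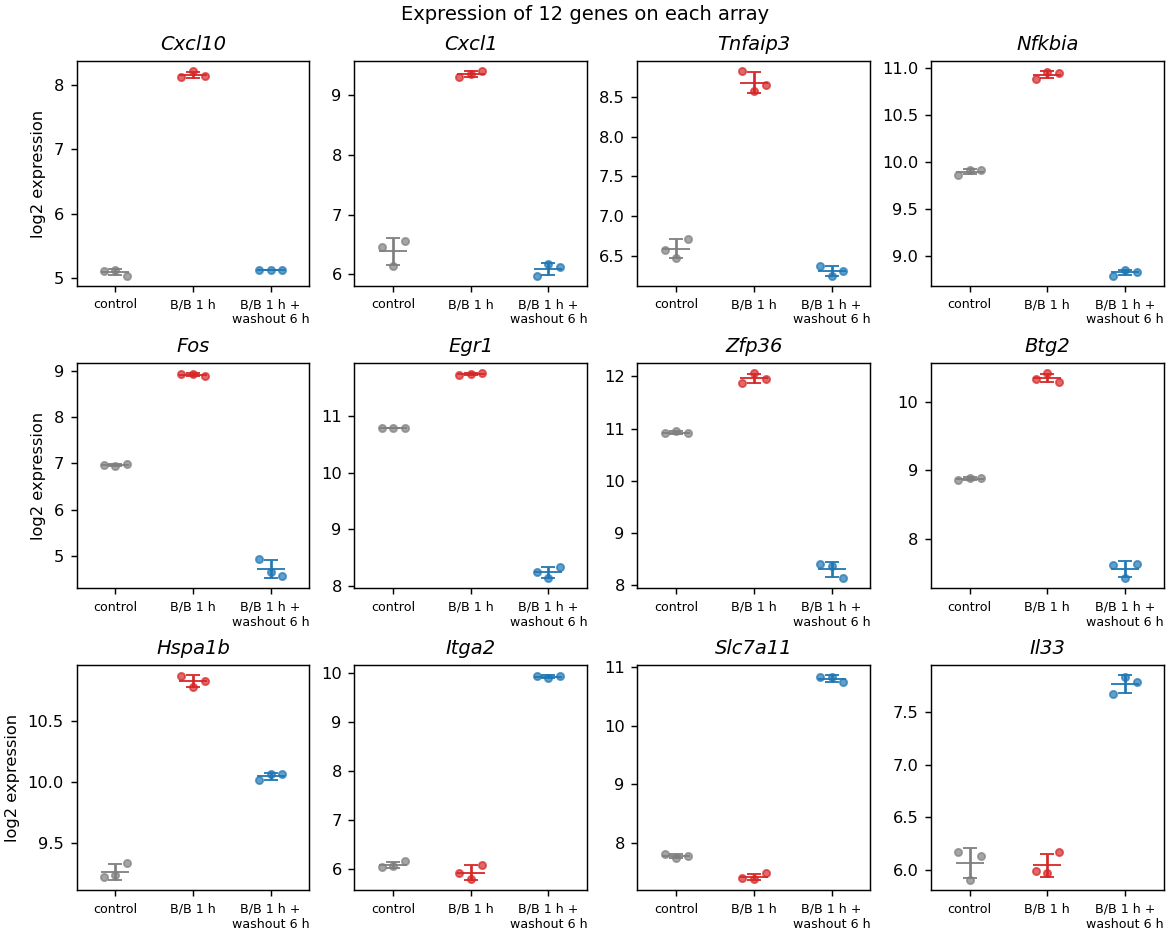
Log2 levels of 12 genes, 1 panel per gene with its own y axis, in the control, B/B 1 h and washout groups; points are arrays and bars the mean ± SD (n = 3). Cxcl10 stood at 5.09, 8.16 and 5.12 in the 3 groups, Fos at 6.97, 8.92 and 4.72, and Itga2 at 6.09, 5.94 and 9.91.

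The comparison of washout with control asked how cells sorted after 1 h of B/B differed from control cells after 6 h of washout. Itga2, a collagen-binding integrin subunit, rose 14.1-fold, from 6.09 ± 0.063 to 9.91 ± 0.029 (log2, SD, n = 3 per group). Slc7a11, which imports cystine for glutathione synthesis, rose 8.19-fold, or by 3.03 (log2), and by 1.89 (log2) with its probe sets averaged. Plat, the tissue plasminogen activator gene, rose 4.88-fold. Zfp36, which encodes a protein that degrades AU-rich cytokine transcripts, decreased by 2.62 (log2), from 10.92 ± 0.026 to 8.31 ± 0.14 (log2, SD, n = 3 per group). Egr1 and Fos, both higher at 1 h, fell below control by 2.55 and 2.24 (log2). The highest limma adjusted p of these 6 genes, after Benjamini-Hochberg adjustment, was 1.6e-07, for Fos.

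After washout, 5814 genes passed the threshold against control, 3208 higher and 2606 lower, and 226 changed at least 2-fold, 132 up and 94 down. The 3 arrays of each group did not overlap in 8425 genes (38.0%), where chance gives 10%. Other genes with the highest values were Plet1, which encodes a membrane-anchored surface protein, at 3.24, and the adhesion molecule Ceacam1 at 2.36. Bpifc, a lipid-binding protein gene, stood at 2.35, the myeloid receptor gene Trem3 at 2.25 and Plek, a platelet and leukocyte kinase C substrate gene, at 2.21 (log2). Among the lowest were the Notch-responsive repressor Hes1 at -2.25, the clock repressors Nr1d1 at -2.22 and Bhlhe40 at -1.94, Fosb at -2.40 and Klf10 at -1.93 (log2).

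Immediate-early genes stood below control after washout, with 8 higher and 25 lower of 38 past the threshold (8 and 25 adjusted over the list alone). Their median was -0.39 (log2) and camera called them down at an adjusted p of 7.0e-09, with adjusted p = 0.0918 with an estimated correlation, the highest of camera alternatives from 3.6e-10. Against the list, Dusp4, a MAP kinase phosphatase gene chosen after its value was seen, was among the 8 that rose, at 0.86 (log2). Chemokines split, with 4 higher and 7 lower of 25 (4 and 8 adjusted over the list alone; camera adjusted p 0.115). Il33, an alarmin that dying cells release, rose by 1.69 ± 0.082, while Ccl7 and Cxcl5, which attract monocytes and neutrophils, fell by 1.55 ± 0.042 and 1.03 ± 0.10 (log2, SE). The other 3 that rose, chosen after their values were seen, were Il1a at 0.73, Il6 at 0.58 and Cxcl2 at 0.34. NF-kB genes had 8 higher and 8 lower of 25 (10 and 9 adjusted over the list alone; camera adjusted p 0.790), with a median of 0.06, a mean of -0.11 and a tested direction of down. Nfkbia, Gadd45b and Zc3h12a, a nuclease that degrades inflammatory transcripts, fell by 1.07, 1.06 and 1.03 (log2).

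Interferon genes had 2 higher and 2 lower of 24 (2 and 2 adjusted over the list alone; camera adjusted p 0.90), with Stat2 at 1.21, its partner Irf9 at 0.29 and the GTPase gene Irgm1 at -0.45 (log2) and Isg20, chosen after its value was seen, at -0.28. The list had a median of -0.01, a mean of 0.03 and a tested direction of down. In the necroptosis list 6 higher and 5 lower of 19 passed (8 and 5 adjusted over the list alone; camera adjusted p 0.979). Tlr3, a receptor for double-stranded RNA, rose by 1.12 ± 0.083, while its adaptor Ticam1 and the deubiquitinase Cyld fell by 0.89 ± 0.075 and 0.99 ± 0.063 (log2, SE). The death receptor genes Tnfrsf1a and Tnfrsf12a, chosen after their values were seen, fell by 0.22 and 0.23. Mlkl fell by 0.49 ± 0.053 (log2, SE; limma adjusted p 9.4e-05), and Ripk3 stood at -0.20 (limma adjusted p 0.314; -0.30 to -0.09 over the alternatives). The unfolded protein and integrated stress list had 7 higher and 9 lower of 26 (7 and 10 adjusted over the list alone; camera adjusted p 0.404), with Trib3, a pseudokinase of the stress response, at 0.66 and Ddit4 at -1.15, a median of -0.07, a mean of 0.02 and a tested direction of down. Heat shock genes had 4 higher and 3 lower of 17 (5 and 3 adjusted over the list alone; camera adjusted p 0.864), with Hspa1b at 0.78 and the co-chaperone genes Hsph1 at 0.38 and Hspa4l at 0.37. Its other moved members, chosen after their values were seen, were Chordc1 at 0.26, Bag3 at -0.32, Stip1 at -0.28 and Hspb8 at -0.16, and the list had a median of -0.02, a mean of 0.05 and a tested direction of up.

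Of ESCRT genes, 14 higher and 4 lower of 29 passed after washout (15 and 6 adjusted over the list alone), with a median of 0.14 (log2). Camera called the list up at an adjusted p of 0.0448, and the call was lost with an estimated correlation (0.441). Chmp1b, an ESCRT-III subunit, rose by 0.90 ± 0.053 and Hgs, which recruits ESCRT-I to endosomes, by 0.69 ± 0.045, while Vps28 of ESCRT-I fell by 0.50 ± 0.050 (log2, SE). The other 3 lower members, chosen after their values were seen, were Mvb12a at -0.25, Vps36 at -0.16 and Snf8 at -0.15. The camera call of the ESCRT list was also lost with quantile normalization (0.0614), array medians centred (0.0529), dim genes left out (0.103) and only the 2 groups compared (0.0643). It was lost as well without control replicate 1 (0.0624), B/B 1 h replicates 1, 2 and 3 (0.0515, 0.0520 and 0.0525) and washout replicates 1 and 3 (0.0551 and 0.0753). Over its camera alternatives the adjusted p ran from 0.0276 to 0.441. Membrane repair genes had 4 higher and 9 lower of 25 (4 and 9 adjusted over the list alone; camera adjusted p 0.0611), with the phospholipid scramblase gene Ano6 at 0.59, the sphingomyelinase gene Smpd1 at -0.48 and the annexin gene Anxa6 at -0.44 (log2). Xkr8, Rab27b and Anxa7, chosen after their values were seen, stood at 0.43, 0.33 and 0.26.

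Antioxidant NRF2 targets were called up after washout, with 10 higher and 1 lower of 16 (10 and 1 adjusted over the list alone), a median of 0.34 and a camera adjusted p of 9.3e-06, or 0.0286 with an estimated correlation. Besides Slc7a11, Hmox1 rose by 0.97 ± 0.048 and Txnrd1, a thioredoxin reductase gene, by 0.88 ± 0.040 (log2, SE). The member that fell was Gclc, a glutathione synthesis gene chosen after its value was seen, at -0.16. Cholesterol genes had 8 higher and 3 lower of 19 (11 and 3 adjusted over the list alone; camera adjusted p 0.115), with the synthesis enzymes Mvd and Dhcr7 at 0.42 and 0.41 and Mvk at -0.32, and Srebf2 and Insig1, chosen after their values were seen, at -0.24 and -0.21. Hypoxia and glycolysis genes had 7 higher and 10 lower of 23 (7 and 11 adjusted over the list alone). Their camera adjusted p was 0.211, and 0.0127 to 0.420 over the camera alternatives. Pfkp, a phosphofructokinase gene, rose by 1.89 ± 0.074, while the mitophagy receptor Bnip3 and the vasodilator peptide gene Adm fell by 1.23 ± 0.063 and 1.08 ± 0.076 (log2, SE). Ndrg1 stood at 0.38 in the probe set used and at -0.47 in its other probe set (adjusted p 0.0460).

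Cell cycle and DNA replication genes fell after washout, with 1 higher and 25 lower of 30 (2 and 25 adjusted over the list alone). Ccnb2, a mitotic cyclin, fell by 0.74 ± 0.065, Birc5, a chromosomal passenger protein gene, by 0.72 ± 0.055 and Cdc6, a replication licensing factor, by 0.72 ± 0.047 (log2, SE). The list's median was -0.33 and its camera adjusted p 1.9e-12, or 0.0286 with an estimated correlation. The member that rose was Ccnd1, a G1 cyclin gene chosen after its value was seen, at 0.15. Extracellular matrix and fibroblast identity genes were also called down, with 4 higher and 17 lower of 29 (5 and 19 adjusted over the list alone), a median of -0.34 and a camera adjusted p of 8.5e-06, or 0.0286 with an estimated correlation. Pdgfrb, a growth factor receptor of fibroblasts, and Thbs1, a matrix glycoprotein, fell by 1.36 ± 0.047 and 1.01 ± 0.044, while the collagenase gene Mmp13 rose by 1.38 ± 0.079 (log2, SE) and Timp1 stood at 0.46. The other 2 that rose, chosen after their values were seen, were Pdgfra at 0.68 and Dcn at 0.23.

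Oxidative phosphorylation genes were called down, with 0 higher and 14 lower of 33 (0 and 18 adjusted over the list alone, 0 and 20 by limma at unadjusted p under 0.05), a median of -0.16 and a camera adjusted p of 3.0e-07, with adjusted p = 0.219 with an estimated correlation, the highest of camera alternatives from 5.0e-08. Ndufa9 of complex I, Sdhc of complex II and Uqcrfs1 of complex III stood at -0.48, -0.47 and -0.40 (log2). The p53 target list was called down, with 3 higher and 6 lower of 18 (3 and 8 adjusted over the list alone) and a camera adjusted p of 0.0409, with adjusted p = 0.206 with an estimated correlation. Its members with the largest values went both ways, with the autophagy gene Trp53inp1 at 0.75, the ribonucleotide reductase gene Rrm2b at 0.63 and the mTORC1 inhibitor Sesn1 at -0.52, and Tigar, chosen after its value was seen, at 0.41. That call was lost with dim genes left out (0.0613) and without control replicates 1 (0.0664) and 2 (0.0604) or washout replicates 1 (0.0658) and 3 (0.0716), within 0.0177 to 0.206 over its camera alternatives. Ribosomal protein genes were called down, with 1 higher and 8 lower of 36 (1 and 8 adjusted over the list alone) and a camera adjusted p of 0.0343, with adjusted p = 0.522 with an estimated correlation. This call was lost with quantile normalization (0.0567), with dim genes left out (0.0575), and without control replicate 2 (0.0567) or washout replicate 1 (0.0561), within 0.00182 to 0.522 over its camera alternatives. Rpl5 and Rpl37 fell by 0.70 and 0.58, Rps20 by 0.53 (log2 difference -0.32 with its probe sets averaged and -0.34 without control replicate 3), and Rpl3, chosen after its value was seen, rose by 0.18 (log2). Nuclear-retained long noncoding RNA had 0 higher and 5 lower of 11 (0 and 5 adjusted over the list alone, 0 and 5 by limma at unadjusted p under 0.05; camera adjusted p 0.0788), with Neat1, the scaffold of paraspeckles, at -1.04, Dleu2 at -0.81 and the snoRNA host Snhg12 at -0.45 (log2), and Malat1 and Airn, chosen after their values were seen, at -0.26 and -0.23.

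Leukocyte markers after washout had 1 higher and 2 lower of 13 (1 and 2 adjusted over the list alone; camera adjusted p 0.951). Cd14 rose by 1.47 ± 0.060 against control (log2, SE), while Lyz2 fell by 0.30 and Ptprc by 0.19, both at low signal that was not told apart from background. Epithelial markers had 0 higher and 1 lower of 12 (0 and 0 adjusted over the list alone, 1 and 2 by limma at unadjusted p under 0.05; camera adjusted p 0.412), the cadherin gene Cdh1 at -0.20, and endothelial markers 1 higher and 0 lower of 11 (1 and 0 adjusted over the list alone, 2 and 0 by limma at unadjusted p under 0.05; camera adjusted p 0.688), Cdh5 at 0.28. The calls of Cdh1, Lyz2, Ptprc and Rps20 were each lost when washout replicate 2 or washout replicate 3 was left out. Those of Cdh1 and Ptprc were also lost without control replicates 1 and 3, that of Lyz2 without control replicates 1 and 2, and that of Rps20 without control replicate 3 and washout replicate 1. Adjusted p without 1 of these arrays reached 0.0986 for Cdh1, 0.0902 for Lyz2, 0.0888 for Ptprc and 0.0859 for Rps20. With its probe sets averaged Cdh1 reached 0.339, and the lowest value over the alternatives of these 4 genes was 0.0123.

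**Figure D3:**
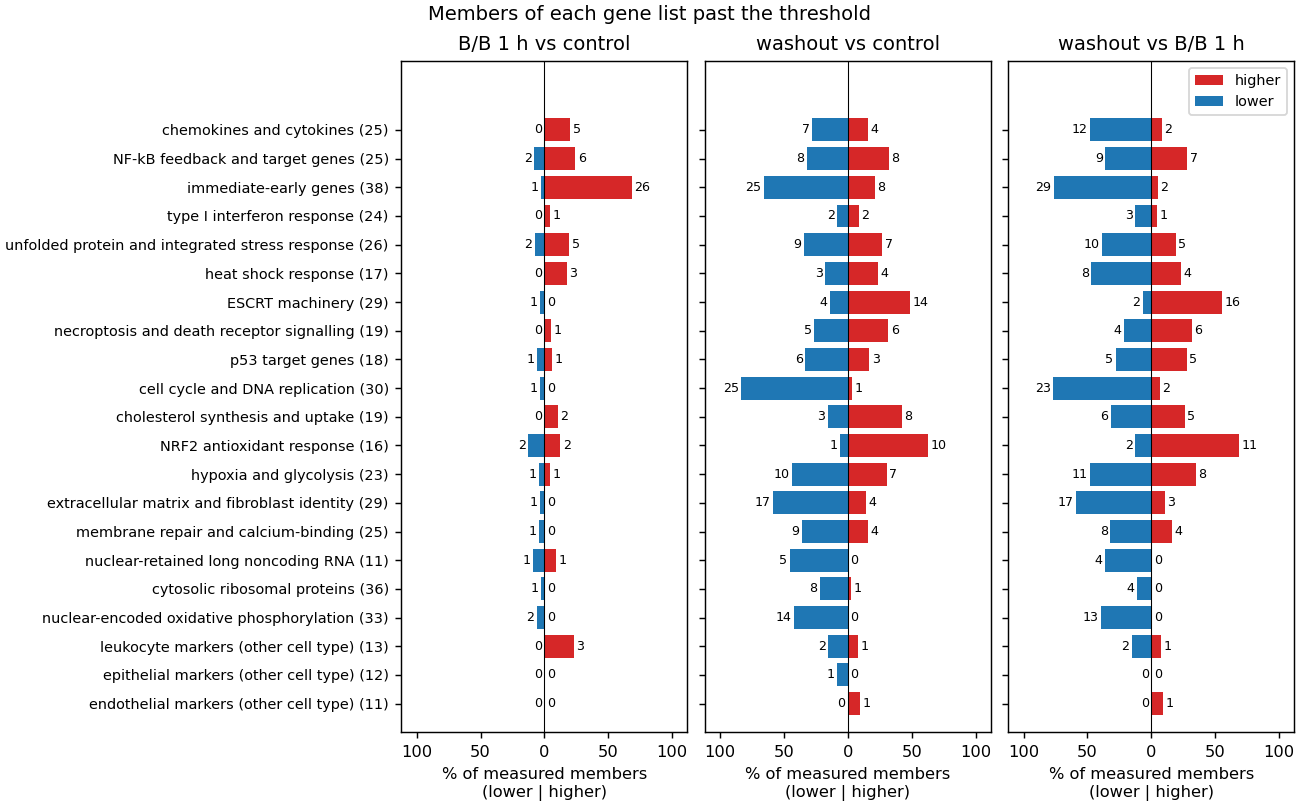
Percent of the measured members of each of 21 gene lists that passed the threshold as higher (to the right of 0) or lower (to the left) in each comparison; numbers beside the bars are counts of genes and those after the names are measured members. Immediate-early genes had 26 of 38 higher at 1 h and 25 of 38 lower after washout, and cell cycle genes 25 of 30 lower after washout.

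The comparison of washout with B/B 1 h asked what changed over the 6 h of washout in cells that had been sorted alike. Only the washout group had the 3000 nM compound and 6 h more in culture after sorting. Effects of the washout, its compound and time therefore cannot be told apart here. Fos fell 18.3-fold, from 8.92 ± 0.030 to 4.72 ± 0.19 (log2, SD, n = 3 per group), and Zfp36 and Egr1 decreased by 3.65 and 3.50 (log2). Cxcl1 and Cxcl10, the top genes at 1 h, fell by 3.24 and 3.04 (log2) and then lay at -0.29 and 0.03 from control. Itga2 and Slc7a11 rose 15.8-fold and 10.5-fold, the latter by 3.39 (log2), or 2.02 with its probe sets averaged, and Kdm7a, a histone demethylase gene, rose by 2.42 (log2). The highest limma adjusted p of these 8 genes was 5.4e-08, for Kdm7a.

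Between 1 h and washout 6345 genes passed the threshold, 3687 higher and 2658 lower, with 178 up and 96 down among 274 that changed at least 2-fold. Groups did not overlap in 8777 genes (39.6%), where chance gives 10%. Immediate-early genes fell, with 2 higher and 29 lower of 38 (4 and 30 adjusted over the list alone), a median of -0.79 and a camera adjusted p of 5.0e-19. Chemokines fell, with 2 higher and 12 lower of 25 (3 and 12 adjusted over the list alone) and a camera adjusted p of 1.6e-04, with adjusted p = 0.0918 with an estimated correlation, the highest of camera alternatives from 2.8e-05. ESCRT genes rose, with 16 higher and 2 lower of 29 (16 and 4 adjusted over the list alone), a median of 0.18 and a camera adjusted p of 0.00384, with adjusted p = 0.322 with an estimated correlation, the highest of camera alternatives from 0.00256. Chmp1b and Hgs rose by 1.07 and 0.67 (log2) over the washout. NRF2 targets rose, with 11 higher and 2 lower of 16 (11 and 2 adjusted over the list alone; camera adjusted p 7.5e-06). Members that went against these 4 lists were chosen after their values were seen, with Dusp4 and Plaur, which encodes the urokinase receptor, both at 0.67, Il33 and Il1a at 1.71 and 0.76, Vps28 and Mvb12a at -0.45 and -0.28, and Osgin1 and Gclc at -0.37 and -0.15 (log2).

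Cell cycle genes fell over the washout, with 2 higher and 23 lower of 30 (2 and 24 adjusted over the list alone; camera adjusted p 1.4e-09), and matrix genes fell, with 3 higher and 17 lower of 29 (4 and 17 adjusted over the list alone; camera adjusted p 1.6e-05). Against them stood Ccnd1 at 0.23 and the mitotic kinase gene Aurka at 0.17, and Mmp13, Timp1 and Pdgfra at 1.55, 0.71 and 0.51, all chosen after their values were seen. These calls and those of the immediate-early and NRF2 lists held with an estimated correlation, each at an adjusted p of 0.0286. Oxidative phosphorylation genes had 0 higher and 13 lower of 33 (0 and 14 adjusted over the list alone, 0 and 17 by limma at unadjusted p under 0.05) and a camera adjusted p of 2.6e-04, with adjusted p = 0.415 with an estimated correlation, the highest of camera alternatives from 8.6e-06. Nuclear-retained long noncoding RNA had 0 higher and 4 lower of 11 (0 and 4 adjusted over the list alone, 0 and 5 by limma at unadjusted p under 0.05) and a camera adjusted p of 0.0486, with adjusted p = 0.372 with an estimated correlation. Its 4 lower members, chosen after their values were seen, were Neat1, Snhg12, Snhg1 and Malat1 at -0.76, -0.56, -0.24 and -0.18. Snhg12 and Snhg1 are snoRNA hosts, so the call is not one of nuclear-retained RNA alone. That last call was lost with quantile normalization (0.0717), dim genes left out (0.0799) and array weights (0.0530). It was lost without control replicate 2 (0.0507), B/B 1 h replicates 1 (0.0670) and 3 (0.0575) and washout replicates 1 and 3 (each 0.0820), within 0.0174 to 0.372 over its camera alternatives. The other 13 lists had camera adjusted p of 0.0788 to 0.833 in this comparison. Among them, NF-kB genes had a median of 0.01 and a mean of -0.32 with a tested direction of down, and p53 targets a median of -0.01 and a mean of 0.03 with a tested direction of down.

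Many of the genes changed at 1 h changed back over the washout. Of 224 genes higher at 1 h, 153 (68.3%) fell between 1 h and washout, among them Cxcl10, Tnfaip3 and Dnajb1, and of 418 lower genes, 262 (62.7%) rose, among them Vegfa, Phlda3 and Mir19a. The sum, 415, stood against 96.3 under independent lists, a baseline that ignores the 3 B/B 1 h arrays that both comparisons share. In 100 simulations of unchanged groups that share those arrays the covariance of the fold changes was -0.00284 where the observed one was -0.0190, and the correlation was -0.501 where the observed one was -0.423. The simulations give no baseline for the count itself. The count of 415 was 251 with only the 2 groups compared and 740 with a variance trend. It was 245, 247 and 220 without control replicates 1, 2 and 3, and 258 without B/B 1 h replicate 1. Some genes went past control, with 56 that were higher at 1 h and lower after washout, such as Fos, Btg2 and Nfkbia, and 133 that were lower and then higher, such as Slc7a11, Kdm7a and Timp1. Others went further in the same direction, 28 up, such as Plat, Plet1 and Cd14, and 58 down, such as Hes1, Bhlhe40 and Gadd45b.

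Against control, 239 genes had the same direction at 1 h and after washout, 73 higher and 166 lower, where independent lists give 32.4 and 49.1. Hmox1, Sqstm1 and Stat2 were higher at both times and Rny3, Snora34 and Hes1 lower at both. Opposite directions were held by 189 genes, where independent lists give 86.8. Both comparisons share the 3 control arrays, and simulated unchanged groups gave a covariance of 0.00283 where 0.00355 was observed, an excess of 0.000719. The correlation was 0.0868 observed and 0.499 simulated, and 3 control arrays cannot be split between the comparisons. The count of 239 was 363 with dim genes left out, 457 with a variance trend and 130 with only the 2 groups compared. Without control replicates 1, 2 and 3 it was 153, 147 and 119, and without B/B 1 h replicates 1 and 2 it was 132 and 125.

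**Figure D4:**
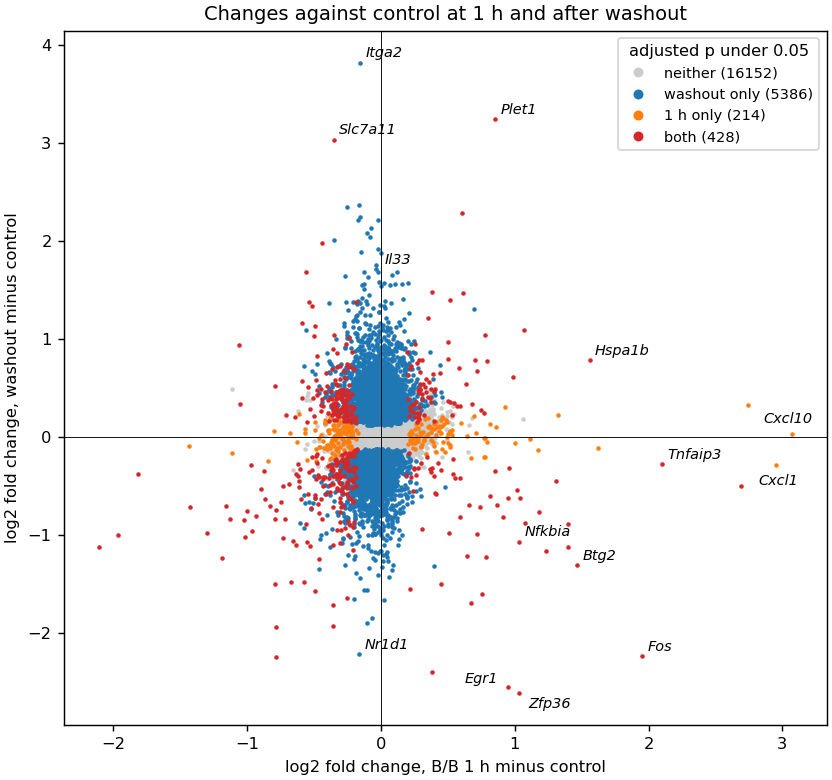
Log2 fold change of 22180 genes at B/B 1 h (x axis) and after washout (y axis), each against control, with 1 point per gene coloured by the comparisons in which it passed the threshold. Of these genes 5386 passed after washout only, 214 at 1 h only and 428 at both, with Cxcl10 near 0 on the y axis at 3.07 on the x axis and Itga2 at 3.82 on the y axis.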

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

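All tests of probe sets without a gene symbol were chosen only after the result was seen. Of 16010 such probe sets, fitted with limma apart from the named genes, 461 passed the threshold at 1 h against control, 161 higher and 300 lower. After washout 757 passed against control, 264 higher and 493 lower, and 1309 passed against B/B 1 h, 651 higher and 658 lower. At 1 h the highest was probe set 17280864, at 2.87 ± 0.058 (log2, SE), and the lowest 17204971, at -2.30 ± 0.19. After washout against control 17417699 stood highest, at 2.88 ± 0.096, and 17270110 lowest, at -2.77 ± 0.25. These 4 were chosen after their values were seen, and what they measure was not analysed here. Probe sets with several symbols, 1814 in number, passed in 94 cases at 1 h (33 higher, 61 lower), 416 after washout against control (200 higher, 216 lower) and 436 against B/B 1 h (249 higher, 187 lower).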

How the results depend on the processing

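The tests of percent higher and of snoRNA genes under other settings were chosen only after the result was seen; groups, comparisons, lists and most alternatives were fixed before the data were examined. No paired analysis was possible because the labels number no replicates across groups. Counts at 1 h moved most. The 642 genes became 1228 with a variance trend, 359 with only the 2 groups compared and 239 at adjusted p under 0.01, which calls fewer genes by construction, and 323 to 691 with 1 array left out. The genes that changed back, 415, became 740, 251 and 168 under the same 3 settings and 220 to 505 with 1 array left out. The overlap against control, 239, became 457, 130 and 78, 363 with dim genes left out and 119 to 198 with 1 array left out. Except for the stricter threshold, the cause was not tested. The percent higher at 1 h, 34.9, was 48.0 with quantile normalization and 35.5 to 46.1 with 1 array left out, and the cause was not tested. Quantile normalization shared 509 of the 642 calls in the same direction, with 0 opposite by limma, where 4096 genes lay at an unadjusted p under 0.05, and median centring shared 600. Larger results moved less, with 5013 to 5902 genes after washout against control, 5505 to 6145 against B/B 1 h, 5619 to 6554 in the F-test and 47 to 57 lower snoRNA genes with 1 array left out. Scaling shifted the median of all genes to between -0.01 and 0.02. Lists called, 7, 8 and 8, fell to 2, 3 and 4 with an estimated correlation, which reached 0.222 where 0.01 was preset. Heat shock genes at 1 h had an estimate of -0.000673, and their camera adjusted p still went from 1.4e-04 to 0.0286. Leukocyte markers at 1 h, with an estimate of 0.00601, went from 0.0263 to 0.147. A correlation above the preset was therefore not the only cause, and the rest was not tested. A call lost with an estimated correlation thus does not by itself show that the members of a list are correlated. With fry, which tests a list against no change and not against the other genes as camera does, 10, 16 and 14 lists passed, which is another quantity. For washout against control the number was 5 with dim genes left out, 5 at adjusted p under 0.01 and 5 to 9 with 1 array left out (5 without washout replicate 1), and the cause was not tested. The unfolded protein list at 1 h, down and not called in camera (adjusted p 0.577), ran from 0.425 to 0.874 over its camera alternatives. Against no change, the other hypothesis that fry tests, it was up at 0.0402, and the cause was not tested. Leaving out 1 array also added calls at 1 h for the interferon list (0.0382 without control replicate 3), oxidative phosphorylation (0.0343, 0.0220 and 0.0372 without control replicate 1, B/B 1 h replicate 2 and B/B 1 h replicate 3) and endothelial markers (0.0358 without B/B 1 h replicate 2). After washout it added membrane repair (0.0457 without washout replicate 3) and nuclear-retained RNA (0.0423, 0.0499 and 0.0344 without control replicate 1, control replicate 3 and washout replicate 2). Over the camera alternatives of these 5 results the adjusted p ran from 0.0220 to 0.613. Averaging probe sets added camera calls for oxidative phosphorylation at 1 h (0.0276) and, after washout against control, hypoxia (0.0127) and membrane repair (0.0414). Testing every probe set added hypoxia (0.0265), membrane repair (0.0311) and nuclear-retained RNA (0.0243) after washout against control. It also added heat shock between washout and B/B 1 h (0.0368). Over 143 results of named genes in limma, called or not, 2713 settings gave the same outcome, 144 a weaker one and 0 a reversed one. Over 63 list tests, those with fry included, 1240 gave the same outcome, 50 a weaker one, 32 a stronger one and 1 a reversed one.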

Other observations

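The tests of clock, contractile, transporter, adhesion, lysosome, zinc finger and snoRNA genes as sets, and those of microRNA, sorting and later harvest, were chosen only after the result was seen. After washout, genes of the circadian clock stood below control, with 11 lower and 2 higher of 15 measured (camera adjusted p 9.7e-07, and 0.0176 with an estimated correlation). Without Nr1d1 and Bhlhe40, already named, 9 were lower and 2 higher of 13 (camera adjusted p 2.8e-04, and 0.0272 with an estimated correlation). Per1, a period repressor, fell by 1.90 ± 0.057, Dbp, a rhythmic activator of clock output, by 1.01 ± 0.12 and Hlf, a related factor, by 0.70 ± 0.065 (log2, SE). Arntl and Clock, which form the activating pair, rose by 1.03 ± 0.081 and 0.18 ± 0.048. Contractile genes fell, with 12 lower and 1 higher of 17 (camera adjusted p 7.7e-10, and 0.00648 with an estimated correlation). Myl9, a myosin light chain gene, fell by 1.65 ± 0.057, Actg2, a smooth muscle actin gene, by 1.49 ± 0.12 and Tagln, an actin-binding protein gene, by 0.69 ± 0.054, while the intermediate filament gene Des rose by 0.33 ± 0.060 (log2, SE). At 1 h, clock genes had 0 higher and 3 lower (0 and 5 by limma at unadjusted p under 0.05, camera adjusted p 3.7e-04, and 0.0350 with an estimated correlation), and contractile genes 0 and 2 (0 and 6 unadjusted, camera adjusted p 0.0908), or 0 and 0 with quantile normalization.

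Of 12 amino acid transporters, a set prompted by Slc7a11, 5 were higher and 0 lower after washout, with a median of 0.09 (5 and 1 by limma at unadjusted p under 0.05, camera adjusted p 0.00131, and 0.0346 with an estimated correlation). Without Slc7a11 the camera adjusted p was 0.0163, with adjusted p = 0.0907 with an estimated correlation. Besides Slc7a11 these were Slc7a1, which carries arginine and lysine, at 0.50, the lysosomal exporter Slc36a1 at 0.45, the glutamine carrier Slc38a1 at 0.35 and the neutral amino acid exchanger Slc1a4 at 0.25 (log2). Adhesion receptors had 9 higher and 4 lower of 22 (camera adjusted p 0.0319, with adjusted p = 0.0779 with an estimated correlation), and the call was lost without Itga2 and Ceacam1, which prompted the set (0.302). Itgb3, an integrin subunit that binds vitronectin, rose by 1.75 ± 0.067 and Selp, an adhesion receptor for leukocytes, by 1.68 ± 0.088 (log2, SE) with Itga2, while Itgb5, Itgb4, Itgb7 and Itga8 fell by 0.55, 0.41, 0.40 and 0.31. Lysosome and autophagy genes had 7 higher and 4 lower of 29 (camera adjusted p 0.421). Zinc finger genes named Zfp were called up after washout, with 180 higher and 22 lower of 370 and a median of 0.21 (camera adjusted p 6.7e-13, and 0.0172 with an estimated correlation), against 3 higher and 20 lower at 1 h (9 and 18 with quantile normalization, 2 and 23 with array medians centred). Their counts after washout were 181 and 21 with quantile normalization and 189 and 19 with array medians centred, and Zfp36, of another kind of zinc finger, was among the lower ones.

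Small nucleolar RNA genes, which guide modification of ribosomal and spliceosomal RNA, were lower after washout in 57 of 80 and higher in 0 (limma, with 62 and 1 at unadjusted p under 0.05 and a median of -0.50, -0.62 to -0.37), and in 55 and 0 under both scalings. At 1 h 5 were higher and 16 lower. The 38 measured genes that span 47 of the lower snoRNA genes had a median of -0.0497 (-0.0963 to 0.00466 with genes taken as independent). They were taken as hosts by position alone, without regard to strand. Of these spanning genes 8 were lower and 5 higher. Where they are the hosts, the values argue against lower levels of host gene transcripts as the whole cause. Whether host genes were transcribed less was not measured, so that stays open. Loss of short RNA of every kind stays open, since 88 microRNA genes above the median level of all genes had 5 higher and 16 lower against control (median -0.0551, -0.131 to 0.000213) but 6 higher and 25 lower against B/B 1 h, with a median of -0.22 where snoRNA genes had -0.19. Probe sets of microRNA genes were also not shown to read the mature, short form, so they may not gauge short RNA. The set was already down at 1 h (median -0.22, -0.31 to -0.12 with genes taken as independent; camera adjusted p 7.8e-10, with adjusted p = 0.0619 with an estimated correlation). From 1 h to washout 30 of 80 were lower and 6 higher past the limma threshold. This argues against a shift already complete at sorting for those 30 genes. For the set as a whole it stays open, since the camera call of this fall (9.2e-05) was lost with an estimated correlation (0.160). Of the lower genes 86.0% (74.2 to 93.7) lay above the median level of all genes, though a level also depends on the probes. Noise of dim probe sets that differs from gene to gene would go both ways. It is argued against by 57 lower and 0 higher of 80. Camera called the snoRNA set down after washout against control (adjusted p 2.5e-18, and 0.0266 with an estimated correlation). Faster turnover or less processing of snoRNA during the washout, and a difference in recovery of this RNA class between samples, may each remain as untested explanations.

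Immediate-early genes stood below control after washout, with 25 of 38 lower, though the camera call was lost with an estimated correlation (adjusted p 0.0918, the highest of camera alternatives from 3.6e-10). There were 24 lower members under quantile normalization and under median centring. The deposited values were already normalized between arrays, so these counts cannot decide whether that first normalization shaped the pattern. The median at 1 h, 0.45 (0.20 to 0.66), lay on the other side of 0 from the median after washout, -0.39. This argued against a lasting shift already complete at sorting. A passing effect of sorting cannot be told apart from one of B/B. Both treated groups were sorted, and the labels do not say whether control cells were. Loss of short-lived transcripts, feedback repression after the rise at 1 h, and an activated state of the control cells at harvest, may each account for the pattern and were not tested.

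Clock output genes, 12 without Arntl, Clock and their relative Npas2, were lower after washout in 11, with a median of -0.62. Their median at 1 h, -0.10 (-0.19 to 0.02), argued against a shift complete at sorting as the cause. A later harvest or a change of medium cannot be told apart from an effect of the treatment: Arntl and Clock, 2 of 3 activators measured, passed as higher while Npas2 stood at -0.08, and the labels give no harvest times. The washout itself may have moved the clock, which was not tested.

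Regrouping the arrays asked whether chance can be excluded, with 1 grouping, the real one, reaching each result. For the 3 pairs of groups 10 splits are too few for a share under 0.05, with 642, 5814 and 6345 genes in the real splits and a highest other of 0 in each (limma, with 4096, 7531 and 8283 genes at an unadjusted p under 0.05 in the real splits). Over 100 regroupings of all 9 arrays only the real one reached the 6542 genes that differed among groups. The highest other was 5089, in 1 of 2 regroupings that kept the washout arrays together, and 48 in the rest. This argues against a random assignment of these arrays to groups. It cannot exclude chance differences between cultures, since the labels do not say whether samples of a group were separate cultures. For the 415 genes that changed back (highest other 42) and the 239 shared changes (highest other 0) most regroupings called no gene in limma at all, so these give no baseline for either count. For the 23 list calls the highest other was 22 and the median 12. A regrouping in which 0 genes differed still called 17 lists, so the count of 23 does not exclude chance for the list calls.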
